A study of Homo sapiens with 4 samples.

How the data were processed

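RNA of A549 cells was analysed in 2 RBM10 wild-type and 2 RBM10 knockdown libraries. Per the labels' protocols, knockdown cells were transduced with a lentiviral shRNA and selected with puromycin, mRNA was selected by its poly-A tail, libraries were made with a stranded TruSeq kit, and all 4 libraries share 1 batch. Per the submitters' processing notes, the genome build was hg38 and STAR 2.6.1 was used. The counter, the annotation, the splicing caller and the use of strand in counting are not given in the sources used here.

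The authors deposited a table of gene expression whose values have the form of RPKM, that is reads scaled by gene length and library depth. The unit is not written in the file and was inferred from the values. The values of a gene at low level were whole multiples of a step that differed between genes and libraries, and the ratio of these steps gave the relative depth of the libraries. Of 980 protein-coding genes with a single exon in GENCODE v29, 17 were in the table (1.73%), against 14211 of 18971 with several exons (74.9%), so the deposited RPKM appear to rest on reads across splice junctions. No value was 0, since a gene without reads holds a small value shared by the libraries. Genes at that shared value numbered 943, 970, 727 and 655 in wild-type replicates 1 and 2 and knockdown replicates 1 and 2. The value could be seen only in the 1302 genes where 2 or more libraries hold it. As counts of genes without reads, these are thus lower limits. The 10 genes with the highest values held 10.8% to 12.3% of a library's sum.

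The authors deposited a second table with the PSI of an examined junction, beside a background junction, as a fraction from 0 to 1, per the file headers. In 572 pairs of events with examined and background junction swapped, the PSI summed to at most 1, with a median of 0.916, and 32.4% of the sums lay within 0.02 of 1. The denominator thus holds further junctions in many events, and the PSI of an inclusion junction and that of a skipping junction are given as such, neither taken as 1 minus the other. The deposited fractions are listed only for events whose spread over the 4 libraries is 0.15 or more, as the values show. For 95.9% of events with all values, that spread was the highest minus the second lowest PSI, which takes no account of the groups. Read counts behind each PSI are not in the table, so their depth is unknown and no interval was computed for a single PSI. Junction ends matched exon boundaries of GENCODE v29 (hg38) in 99.95% of 6510 cases, and coordinates are given in that build. Gene names came from a table of gene IDs for 16921 of 17041 IDs and from GENCODE v29 for 85 more, and 35 had none.

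Expression was compared on log2(RPKM + 1) for genes with a mean of 1 RPKM or more in at least 1 group, with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariate. PSI fractions were compared with limma in the 3744 events with a value in all 4 libraries, and an event passed at an adjusted p under 0.05 and a difference of 0.1 or more. An examined junction of a cassette exon counted as inclusion when it lay inside the span of the background junction and as skipping when it contained it, and 1 event was kept per gene and exon, that with the largest difference. For counts, the sign of a skipping junction was turned, and the counts were also made from inclusion junctions alone. Shares of exons were compared with 50% by exact binomial tests, and shares of event types and overlaps of genes by Fisher's exact test.

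Before the data were examined, 30 gene lists and 6 splicing lists were fixed. Gene lists with 5 or more tested members (23 of them) were compared with the other genes by limma's camera with a preset correlation of 0.01, and by camera with an estimated correlation and by fry. Genes to be named were fixed by a rule written beforehand. They were RBM10 and its relatives, the 12 genes with the largest increase and the 12 with the largest decrease among those past the test without overlap of the groups, up to 4 members of each list, events past the test, events of known RBM10 targets, and up to 4 genes of each other splicing list. Members that went against their list and 9 cassette exons were named after their values were seen, and the text on the exons says so.

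The limma tests were first run on simulated data with known changes, while camera, fry, and the binomial and Fisher tests were not. In expression, limma recovered 26%, 71% and 98% of genes given log2 changes of 0.585, 1 and 2, with 3 false calls among 9823 unchanged genes. In splicing, it recovered 0% of events given changes of 0.2, 0.4 or 0.6 after adjustment, and 5.53% of unchanged events passed without adjustment. The simulated noise came from listed events, already past the filter on spread, and was filtered again. Simulated unchanged events had a median absolute difference of 0.114. In the data it was 0.0698 and 0.0778 between library pairs that mix wild type and knockdown, so the simulation may understate recovery.

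To look for sequence signs of off-target action of the shRNA, each word of 7 bases was tested for association between its presence in the longest annotated 3' UTR of a gene (GENCODE v29) and the gene's change, with UTR length, GC content and expression level as covariates, over 9410 of the tested genes (92.4%) and 15246 words found in 100 or more of them. On simulated data, 10 of 10 words given a log2 effect of -0.1 came out as the lowest, and 5 of 10 given -0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, this scan and plots.

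Alternatives written at the same time as the lists were the replicate number as a block, a pseudocount of 0.1, no filter or a filter of 5 RPKM, quantile normalization, TMM-like factors, other empirical Bayes settings, at least 2-fold changes, PSI on a bounded logit scale (0.01 to 0.99), a difference of 0.2, p without adjustment, 1 event per gene, events with missing values, and leaving out each library. Cyclic loess normalization, a crossed pairing of replicates, list tests under other scalings, the splicing alternatives at an unadjusted p and the counts by kind of junction were added after the data were seen. Reads and per-junction counts were not analysed here.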

Results

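Polyadenylated RNA was sequenced from A549 cells, a human lung adenocarcinoma line, in 4 libraries. In 2 libraries the cells were RBM10 wild type, and in 2 the cells carried a lentiviral shRNA against RBM10, an RNA-binding protein that regulates alternative splicing. Knockdown cells had been selected with puromycin for 10 to 14 days, per the labels. Each library had about 40000000 paired reads of 100 bp, per the labels. Gene expression was read as RPKM of 17041 genes, and splicing as the PSI of 3768 junction events in 2166 genes, where PSI is the share of reads that use the examined junction, in a set of junctions that can hold more than the examined and the background one. Relative to the deepest library, depth was 99.0% and 100% in wild-type replicates 1 and 2, and 84.5% and 95.6% in knockdown replicates 1 and 2. Genes at 1 RPKM or more numbered 9629, 9502, 9967 and 10113 in the same order. The comparison of knockdown with wild type asks which transcripts and which splice choices differ in A549 cells with less RBM10.

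RBM10 mRNA (chromosome X, 47144869 to 47186813, hg38) was at 35.5 and 40.8 RPKM in the wild-type libraries and at 11.6 and 10.9 RPKM in the knockdown libraries, which left 29.5% of the wild-type mean. Its log2 change was -1.67 (SE 0.11; limma, BH adjusted p = 1.01e-05), in the direction the labels give. RBM5 and RBM6, close relatives of RBM10, were at 7.40 ± 0.447 and 5.12 ± 0.643 RPKM in wild type and at 8.05 ± 0.616 and 4.69 ± 0.718 RPKM in knockdown (SD, n = 2 each). Neither passed limma's test (adjusted p = 0.539 and 0.601).

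In knockdown cells, 13 of 16 mesenchymal and matrix genes and 11 of 17 TGF-beta targets rose, and 12 of 24 NRF2 targets fell, with camera adjusted p = 2.87e-10, 0.000558 and 4.8e-08 at a preset correlation between genes. With an estimated correlation these lists did not pass (adjusted p = 0.261, 0.369 and 0.261). On the log2(RPKM + 1) scale, which ranks genes at low levels down, the largest increase was in TM4SF4, a tetraspanin-like membrane protein, which was at 6.30 ± 0.0346 RPKM in wild type and at 90.8 ± 0.126 RPKM in knockdown (SD, n = 2 each). Among the largest increases were the fibrillar collagen genes COL3A1, from 1.61 ± 0.128 to 17.2 ± 1.88 RPKM, COL5A1, from 16.2 ± 1.19 to 86.6 ± 7.37 RPKM, and COL11A1, from 4.91 ± 0.275 to 27.5 ± 3.40 RPKM. On that scale, the largest decrease was in OSGIN1, an oxidative stress response gene, which was at 27.2 ± 3.46 RPKM in wild type and at 6.69 ± 0.327 RPKM in knockdown.

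In limma with Benjamini-Hochberg adjustment, 2271 of 10182 tested genes changed, 1555 higher and 716 lower in knockdown, and 243 of the higher and 30 of the lower genes changed at least 2-fold, or 544 and 58 with a pseudocount of 0.1. Changes are on the log2(RPKM + 1) scale, which understates those of genes at low levels. The share of higher genes among those called was 68.5% and depended on scaling, since quantile normalization gave 1140 higher and 1031 lower genes, a share of 52.5%. Knockdown and wild type separated along the leading principal component, which held 80.8% of the variance. These p-values measure only the spread between these 4 libraries, which may be technical, since nothing in the labels says that replicates came from separate cultures. The labels do not say whether the wild-type cells received a control construct or puromycin, so an effect of RBM10 loss could not be separated here from one of transduction or selection.

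**Figure D1:**
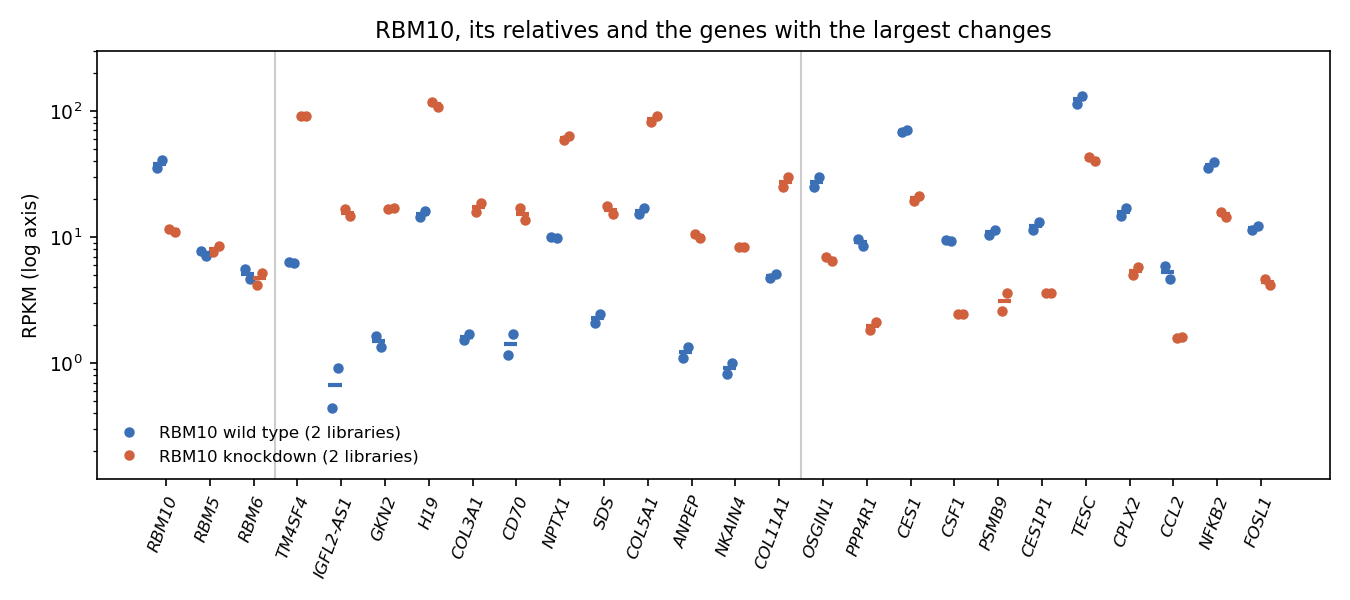
RPKM on a log axis of RBM10, its relatives RBM5 and RBM6, and the genes with the largest increases (middle) and decreases (right) among those past limma's test; points are libraries, blue for wild type and orange for knockdown, and short lines are group means. RBM10 lay at 35.5 and 40.8 RPKM in wild type and at 11.6 and 10.9 RPKM in knockdown.

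Higher and lower values also went with expression level. Over all 17041 genes, the median log2 ratio of knockdown to wild type was 0.53 among the 2218 genes at the lowest level, of which 70.7% were higher, and -0.10 among the 680 at the highest level.

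**Figure D2:**
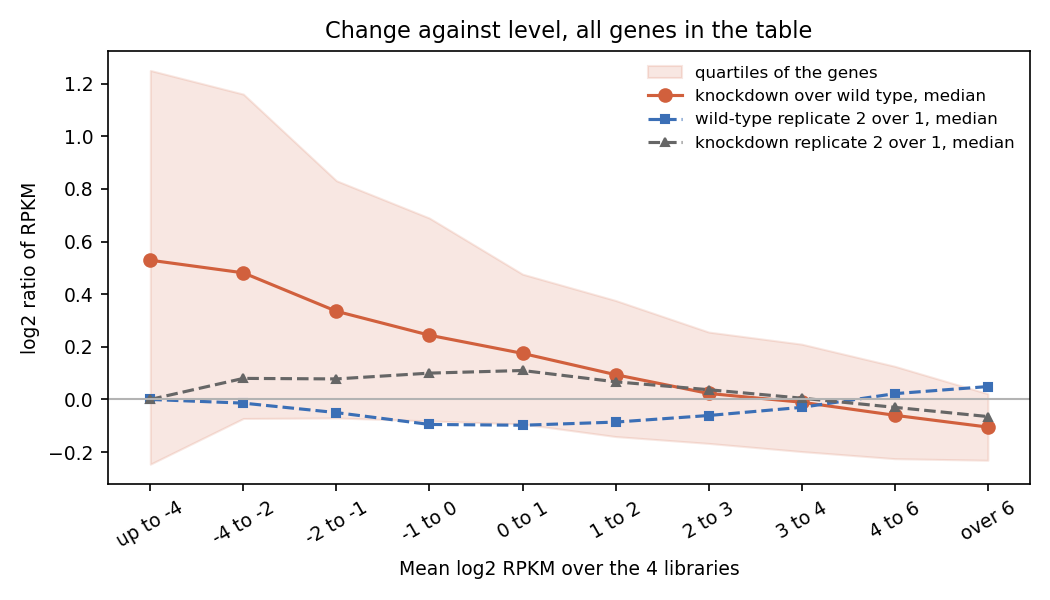
Median log2 ratio of knockdown to wild type over all genes in the table, in bins of mean log2 RPKM (orange line, with quartiles of the genes shaded), and the same ratio between the replicates of each group (dashed lines). The median was 0.53 in the lowest bin and -0.10 in the highest, and medians between replicates stayed within 0.11.

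The other genes with the largest increases were of several kinds. H19, an imprinted long noncoding RNA, was at 15.3 ± 1.21 RPKM in wild type and at 113 ± 6.43 RPKM in knockdown (SD, n = 2 each), with a log2 change of 2.80. The antisense RNA IGFL2-AS1 was at 0.674 ± 0.331 and 15.6 ± 1.38 RPKM, GKN2, a gastric secreted protein, at 1.50 ± 0.213 and 17.0 ± 0.222 RPKM, and CD70, a ligand of the TNF family, at 1.43 ± 0.389 and 15.3 ± 2.32 RPKM. NPTX1, a neuronal pentraxin, went from 9.94 ± 0.0576 to 61.1 ± 2.69 RPKM, and SDS, serine dehydratase, from 2.27 ± 0.279 to 16.5 ± 1.81 RPKM. The aminopeptidase gene ANPEP (1.22 ± 0.182 and 10.2 ± 0.518 RPKM) and NKAIN4 (0.909 ± 0.130 and 8.34 ± 0.00947 RPKM) completed the 12. Their adjusted p-values in limma lay between 8.42e-08, for TM4SF4, and 3.98e-06, for CD70.

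Among the 12 genes with the largest decreases were RBM10 itself, PPP4R1, a regulatory subunit of protein phosphatase 4, from 9.07 ± 0.831 to 1.96 ± 0.208 RPKM, and the carboxylesterase gene CES1, from 69.3 ± 2.31 to 20.2 ± 1.34 RPKM (SD, n = 2 each). CES1P1, a pseudogene of CES1 that may share reads with it, went from 12.3 ± 1.22 to 3.57 ± 0.00227 RPKM. Also in this group were CSF1, a growth factor (9.34 ± 0.0764 and 2.45 ± 0.0248 RPKM), the immunoproteasome subunit PSMB9 (10.9 ± 0.772 and 3.09 ± 0.715 RPKM), the chemokine CCL2 (5.26 ± 0.897 and 1.59 ± 0.0290 RPKM) and NFKB2, a subunit of NF-kB (37.3 ± 2.54 and 15.1 ± 1.02 RPKM). The others were TESC (123 ± 12.9 and 41.9 ± 2.03 RPKM), CPLX2 (15.7 ± 1.65 and 5.36 ± 0.562 RPKM) and FOSL1, a subunit of the AP-1 transcription factor (11.7 ± 0.622 and 4.40 ± 0.314 RPKM). RBM10, RBM5, RBM6, IGFL2-AS1, H19, COL3A1, CD70, SDS, COL5A1, NKAIN4, PPP4R1 and PSMB9 overlap an annotated gene on the opposite strand. Whether the counting used strand is not stated, so their values could hold reads of the partner.

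Gene lists fixed before the data were examined were compared with all other tested genes by camera, with BH adjustment over 23 lists. With a preset correlation between genes of 0.01, 10 lists passed. With a correlation estimated from these libraries 0 passed in camera, although 2 lists had an unadjusted p under 0.05, so no call held in both versions. The estimate was below the preset value in the mesenchymal (-0.0593), NRF2 (-0.0215) and p53 (-0.0416) lists. A higher correlation is thus not why these lost their calls, and 4 libraries leave the estimated version little power. In the other lists that passed, the estimate was above the preset value. The rotation test fry, which asks only whether a list's genes move, on balance, one way, passed 11 lists. Mesenchymal and matrix genes were higher: 13 of 16 rose and 1, SNAI1, fell (adjusted p = 2.87e-10; adjusted p = 0.261 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell. FN1, fibronectin, was at 23.2 ± 1.96 RPKM in wild type and 113 ± 14.0 RPKM in knockdown, and COL1A1 at 3.65 ± 0.0974 and 18.5 ± 0.413 RPKM. TGF-beta targets rose in 11 of 17 cases and fell in 3, ID1, ID2 and SMAD6 (adjusted p = 0.000558; adjusted p = 0.369 with an estimated correlation), with 11 and 3 adjusted over the list alone. LTBP2 was at 2.04 ± 0.223 and 11.5 ± 1.00 RPKM, PMEPA1, a TGF-beta feedback gene, at 10.5 ± 1.04 and 36.1 ± 1.37 RPKM, and COL4A1, of basement membrane collagen, at 19.8 ± 0.158 and 69.1 ± 8.96 RPKM.

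Epithelial genes were also higher, so that mesenchymal and epithelial markers rose together. Of 12 tested epithelial genes, 7 rose and 1, CLDN1, fell (adjusted p = 0.00193; adjusted p = 0.369 with an estimated correlation), and 8 rose and 1 fell adjusted over the list alone. KRT18 went from 932 ± 58.2 to 1793 ± 88.1 RPKM, KRT8 from 348 ± 32.0 to 677 ± 16.0 RPKM, KRT19 from 8.44 ± 1.07 to 21.3 ± 0.852 RPKM and CLDN7, a claudin, from 0.302 ± 0.0544 to 2.14 ± 0.232 RPKM. Of 21 p53 targets, 11 rose and 2, GDF15 and CCNG1, fell, with the same counts adjusted over the list alone (adjusted p = 0.00833; adjusted p = 0.369 with an estimated correlation). The list did not pass when knockdown replicate 1 was left out (adjusted p = 0.0915), and 6 members rose under quantile normalization. DDB2, a DNA damage recognition protein, was at 16.0 ± 0.867 and 28.4 ± 0.256 RPKM, and CDKN1A, the cell cycle inhibitor p21, at 13.7 ± 1.57 and 22.7 ± 1.02 RPKM.

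NRF2 targets, which encode antioxidant and detoxifying enzymes, were lower: 12 of 24 fell and 0 rose (adjusted p = 4.8e-08; adjusted p = 0.261 with an estimated correlation), and 13 fell adjusted over the list alone. AKR1B10, an aldo-keto reductase, was at 2728 ± 58.8 RPKM in wild type and 1375 ± 94.1 RPKM in knockdown, SRXN1, sulfiredoxin, at 22.0 ± 0.459 and 9.74 ± 0.491 RPKM, and GCLC, of glutathione synthesis, at 30.8 ± 3.80 and 16.1 ± 1.55 RPKM. SR proteins, which promote exon inclusion at many exons, fell in 5 of 12 cases and rose in 0 (adjusted p = 0.00113; adjusted p = 0.369 with an estimated correlation), and 7 fell adjusted over the list alone, while 2 fell under cyclic loess normalization. TRA2A was at 19.8 ± 2.59 and 12.8 ± 0.907 RPKM and SRSF2 at 36.7 ± 0.819 and 27.4 ± 0.0270 RPKM. Of 25 hnRNP and other splicing regulators, 2 rose, MBNL2 and PTBP3, and 3 fell, U2AF2, HNRNPD and HNRNPH1 (adjusted p = 0.00833; adjusted p = 0.649 with an estimated correlation), while 2 rose and 6 fell adjusted over the list alone. U2AF2, which recognises the 3' splice site, went from 161 ± 15.8 to 84.3 ± 6.60 RPKM. The regulator list did not pass under quantile or cyclic loess normalization, where 1 member fell in each (adjusted p = 0.119 and 0.133), in fry (adjusted p = 0.283), or without wild-type replicate 1 or knockdown replicate 1 (adjusted p = 0.12 and 0.0915). With TMM-like factors, 6 regulators fell.

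Proliferation genes fell in 6 of 30 cases and rose in 0, and 9 fell adjusted over the list alone (adjusted p = 0.00094; adjusted p = 0.369 with an estimated correlation). The list did not pass under quantile or cyclic loess normalization (adjusted p = 0.061 and 0.0564), with 4 and 3 members lower, or in fry (adjusted p = 0.131). CDC6, of replication licensing, was at 23.1 ± 1.61 and 16.0 ± 1.08 RPKM and CCNE1, cyclin E1, at 16.3 ± 0.456 and 11.4 ± 0.148 RPKM. Hypoxia and glycolysis genes went both ways, with 3 higher and 7 lower of 21, or 3 and 9 adjusted over the list alone (adjusted p = 0.00833; adjusted p = 0.489 with an estimated correlation, and 0.119 under quantile normalization). The glucose transporter gene SLC2A3 rose from 4.50 ± 0.752 to 15.5 ± 0.591 RPKM, and CA9, a carbonic anhydrase, fell from 4.90 ± 0.0584 to 1.68 ± 0.133 RPKM. The hypoxia list did not pass camera under cyclic loess normalization (adjusted p = 0.133) or with the replicate number as a block (adjusted p = 0.0502), nor fry (adjusted p = 0.0904). It also did not pass without wild-type replicate 2 or knockdown replicate 2, where little power is left. The 680 genes at the highest level had a median log2 ratio of -0.105, as described above. Of 39 ribosomal protein genes, with a median log2 change of -0.104, 0 passed limma's test, over all genes or adjusted over the list alone. Their list passed camera as lower (adjusted p = 0.00113; adjusted p = 0.681 with an estimated correlation), did not pass under quantile normalization (adjusted p = 0.242), in fry (adjusted p = 0.297), or without wild-type replicate 2 or knockdown replicate 2 (adjusted p = 0.132 and 0.145), and turned to the other direction under cyclic loess normalization (adjusted p = 0.925).

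**Figure D3:**
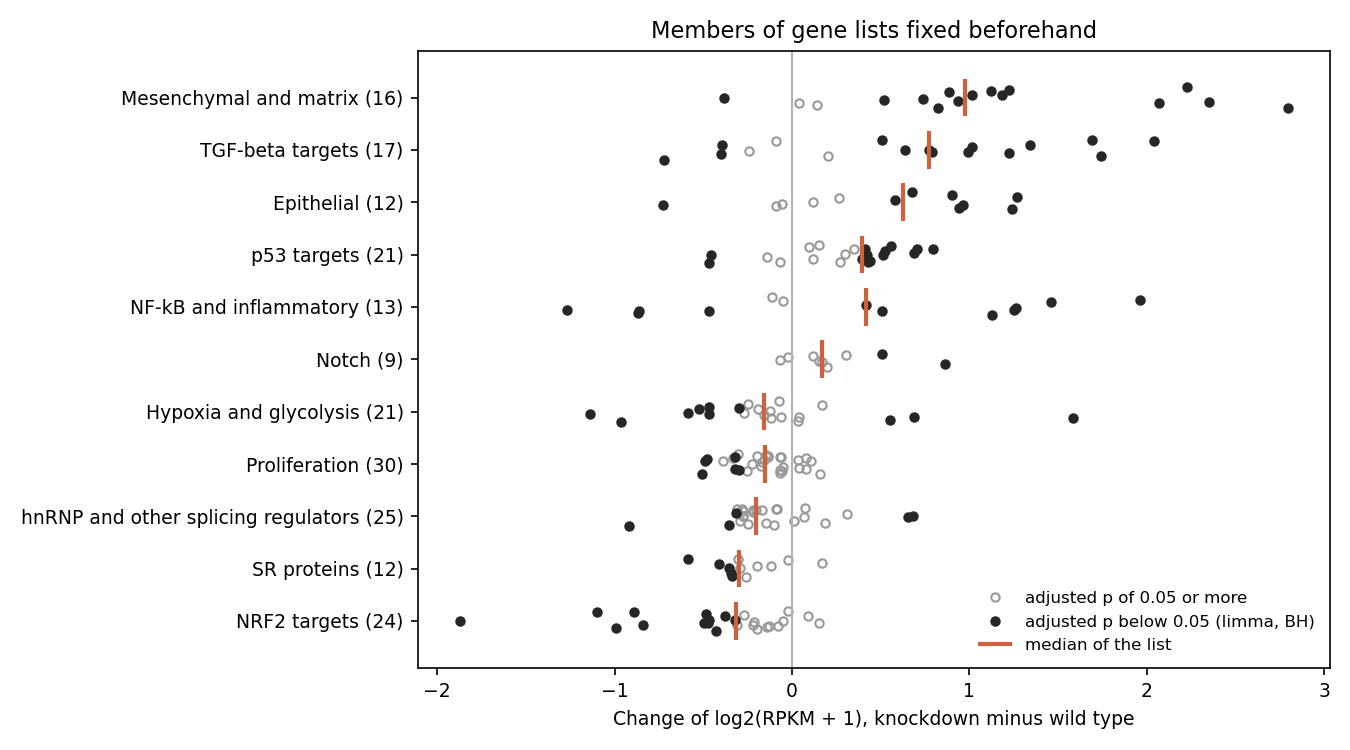
Change of log2(RPKM + 1), knockdown minus wild type, of each tested member of 11 gene lists, with the number tested in brackets; filled points have an adjusted p below 0.05 in limma, open points do not, and orange bars are list medians. Mesenchymal genes lie to the right, with 13 of 16 higher, and NRF2 targets to the left, with 12 of 24 lower.

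Inflammatory genes split, and their list did not pass camera (adjusted p = 0.484), although it passed as higher without knockdown replicate 2 (adjusted p = 0.0241) and in fry (adjusted p = 0.0497). Of 13 NF-kB and inflammatory genes, 7 rose and 4 fell, with the same counts adjusted over the list alone. The cytokine IL11 went from 6.51 ± 1.60 to 28.0 ± 2.71 RPKM and the neutrophil chemokines CXCL1 and CXCL8 from 2.02 ± 0.483 to 7.36 ± 1.74 RPKM and from 0.819 ± 0.127 to 3.37 ± 0.236 RPKM. CCL2, RELB, BIRC3 and NFKBIA fell. Of 9 Notch components and targets, 2 rose and 0 fell (camera adjusted p = 0.172; fry adjusted p = 0.0203), HES4 from 18.7 ± 3.45 to 34.6 ± 3.99 RPKM and NOTCH3 from 9.41 ± 0.317 to 13.8 ± 0.106 RPKM, with 2 adjusted over the list alone. HES1 was at 5.53 ± 0.488 and 7.04 ± 0.0551 RPKM and did not pass (adjusted p = 0.0836).

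In the splicing table, 4 of 3744 tested events passed limma's test on the PSI fractions, at an adjusted p under 0.05 and a difference of 0.1 or more. Of these, 3 were higher and 1 was lower, and all were events of PTP4A2 and MAFK that the authors' table annotates as intron retention. PTP4A2 encodes a protein tyrosine phosphatase. Reads into its intron at chromosome 1, 31938059 to 31938119, had a PSI of 0% in both wild-type libraries and of 93.4% and 96.1% in the knockdown libraries, and the spliced junction went from 92.7% ± 1.47 to 3.40% ± 1.40 (SD, n = 2 each; limma, adjusted p = 0.0354). MAFK encodes a small MAF transcription factor that pairs with NRF2. Reads into its intron 5 at the edge of exon 6 (chromosome 7, 1542298 to 1542299) had a PSI of 0% in both wild-type libraries and of 85.0% and 90.4% in the knockdown libraries (limma, adjusted p = 0.0354). The background junction there starts inside the same intron, at 1542168, so the event does not compare retention with the exon-to-exon splice. MAFK mRNA rose from 13.0 ± 0.269 to 20.4 ± 0.453 RPKM, and PTP4A2, at 27.8 ± 0.904 and 24.1 ± 1.22 RPKM, did not pass. With any single library left out, the differences in reads into the intron stayed between 0.934 and 0.961 for PTP4A2 and between 0.85 and 0.904 for MAFK. No event then passed adjustment, where the smallest adjusted p in limma was 0.345 to 0.439, and 2 against 1 libraries leave this test little power. On simulated data with changes of 0.2, 0.4 or 0.6 in PSI the same test recovered 0% of changed events. The simulated noise was wider than that of the data, so recovery in the data is not known. The count of 4 thus says little about how many events changed. Pairs that mix wild type and knockdown gave 3 and 1 events past the same adjusted test, so the count of 4 does not by itself set the knockdown apart. Zeros of this kind were not particular to PTP4A2 and MAFK. Among 300 retention events, 34 had a PSI of 0 in both wild-type libraries and above 0 in both knockdown libraries. The reverse held for 4 events, and 5 to 21 had such zeros in other pairs of libraries. The depth behind each PSI is unknown, because the table gives no read counts.

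Without adjustment, 689 events (18.4% of those tested, in 462 genes) had a p under 0.05 and a difference of 0.1 or more, against 5.53% of unchanged events in simulated data with wider noise. Mixed pairs gave 64 and 101 events (1.71% and 2.70%), but they hold the difference between the groups in their error, which lowers their counts. The median absolute difference in PSI, which does not depend on that error, was 0.144 between knockdown and wild type and 0.0698 and 0.0778 between mixed pairs. An exon counted as more included when the PSI of its inclusion junction was higher or that of its skipping junction lower in knockdown. Of 1311 cassette exons whose direction could be read, 163 were more included and 92 less included at that level, or 63.9% more included (95% Clopper-Pearson interval 57.7% to 69.8%; exact binomial test, two-sided, p = 1.03e-05), and 0 passed after adjustment. From inclusion junctions alone, 121 exons were more and 79 less included (60.5%, 53.4% to 67.3%; exact binomial p = 0.00363). Over all 1311 exons, whatever their p, 706 were more and 605 less included (53.9%; exact binomial p = 0.0057). Exons of the same gene are not independent, so these p-values are descriptive.

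Individual exons showed large differences, although none of those named here passed the adjusted test. The following 9 exons were chosen after their values were seen, from those with the largest differences. A 204-bp coding exon of VCL (chromosome 10, 74111909 to 74112112), which marks the muscle form of vinculin, had an inclusion junction at a PSI of 1.21% ± 0.752 in wild type and 28.6% ± 1.63 in knockdown, and a skipping junction at 96.8% ± 0.556 and 52.3% ± 0.243 (SD, n = 2 each). The values that follow are PSI of an inclusion junction unless skipping is named. A 90-bp coding exon of R3HDM1 (chromosome 2, 135616668 to 135616757) was at 29.8% ± 9.21 and 88.5% ± 8.76, and a 105-bp coding exon of SEC24B, of vesicle transport (chromosome 4, 109481677 to 109481781), at 28.2% ± 7.88 and 69.2% ± 6.67. An exon of MTMR1 went from 17.6% ± 8.32 to 75.7% ± 6.06, the skipping junction of an exon of ZNF530 from 80.8% ± 5.44 to 13.9% ± 2.04, and an exon of WNK2 (chromosome 9, 93256299 to 93256454) from 53.8% ± 8.75 to 97.6% ± 3.37. In the other direction, the skipping junction of a noncoding exon of ZBTB14 (chromosome 18, 5293972 to 5294001) was at 11.3% ± 9.26 and 60.1% ± 16.8, a 133-bp coding exon of PCNX1 (chromosome 14, 70988567 to 70988699) at 72.9% ± 5.12 and 40.5% ± 2.59, and a 123-bp coding exon of SLC30A5, a zinc transporter (chromosome 5, 69100807 to 69100929), at 83.8% ± 5.30 and 52.4% ± 2.43. Their adjusted p-values in limma lay between 0.111 and 0.259.

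**Figure D4:**
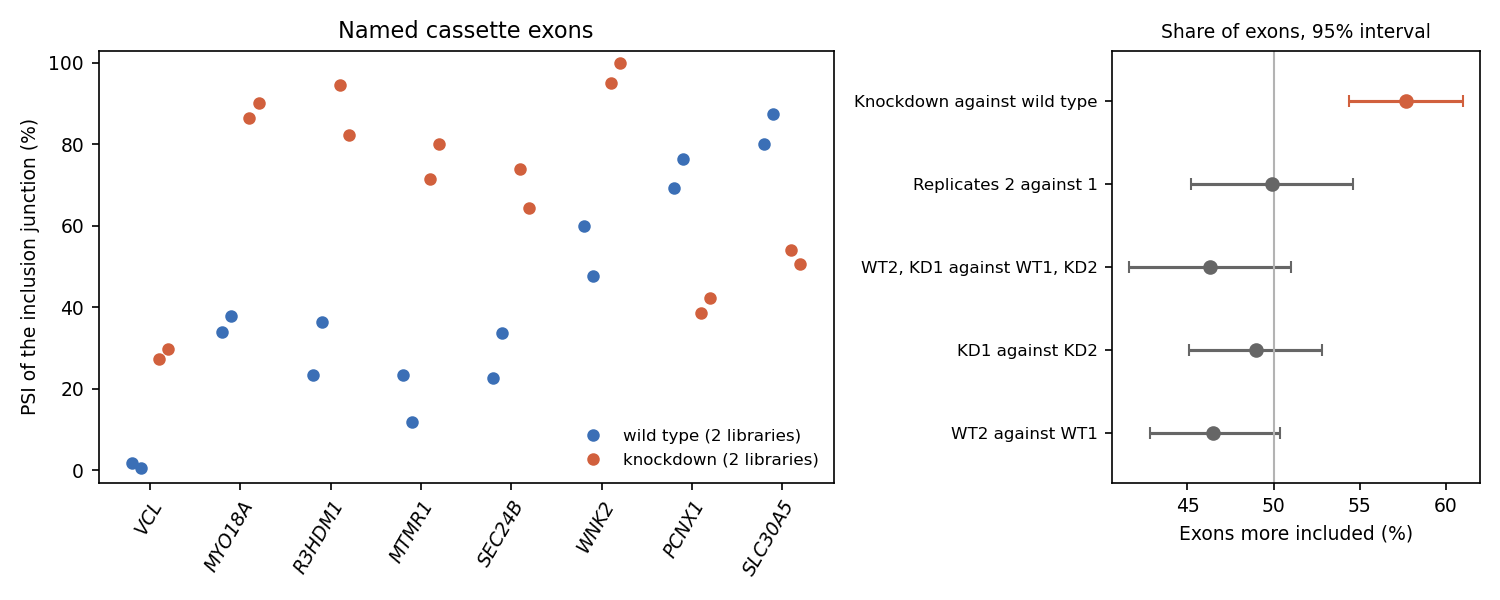
Left, PSI in percent of an inclusion junction of named cassette exons in each library, blue for wild type and orange for knockdown. Right, the share of cassette exons with higher inclusion among those that differ by 0.1 or more in PSI, with 95% Clopper-Pearson intervals, for the comparison of knockdown with wild type and for comparisons that mix or stay within the groups; the former is 57.7% and the others lie between 46.3% and 49.9%.

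Splicing lists, fixed at the same time as the gene lists, held few testable events, and 0 genes of any of the 6 lists passed after adjustment over all events. Of 7 known RBM10 targets, 2 had an event. In NUMB, a Notch regulator, the 144-bp coding exon at chromosome 14, 73279281 to 73279424, had a skipping junction at a PSI of 45.1% ± 9.93 in wild type and 32.4% ± 4.39 in knockdown (SD, n = 2 each; limma, adjusted p = 0.42), a difference that did not pass. An inclusion junction of a 33-bp exon of NUMB was at 38.1% ± 16.8 and 32.1% ± 0.893 (adjusted p = 0.761), and an event of RBM6 was at 65.6% ± 11.6 and 60.5% ± 6.75 (adjusted p = 0.784). Adjusted over the list alone, 0 events of this list passed, 4 of apoptosis genes did and 3 of cytoskeleton and trafficking genes did, with 0 in the splicing factor, EMT and cancer lists.

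The cytoskeleton events were all of a 12-bp coding exon of MYO18A, an unconventional myosin (chromosome 17, 29116444 to 29116455), where the PSI of an inclusion junction went from 35.9% ± 2.71 to 88.3% ± 2.67 in the event with the largest difference. In the apoptosis list, an inclusion junction of a 60-bp coding exon of MADD (chromosome 11, 47288968 to 47289027) was at 17.7% ± 3.62 and 49.0% ± 7.45, and a C-terminal event of CFLAR, the caspase-8 inhibitor c-FLIP, had a PSI of 89.4% ± 1.32 and 49.4% ± 18.5. The apoptosis events that passed over the list alone were of MADD and CFLAR only, and those of MADD read the same exon. Adjustment over a list treats such linked events as separate. In other lists, PSI of an inclusion junction was at 26.0% ± 0.172 and 59.3% ± 10.8 for an 18-bp coding exon of MACF1 (chromosome 1, 39465095 to 39465112), with a 78-bp exon of RALGPS2 (chromosome 1, 178892230 to 178892307) at 9.09% ± 6.43 and 43.5% ± 14.3, and a 90-bp exon of BIN1 (chromosome 2, 127051154 to 127051243) at 53.4% ± 5.42 and 75.8% ± 1.19. A C-terminal event of HNRNPA2B1 had a PSI of 39.7% ± 0.748 and 71.7% ± 9.60. Adjusted over all events in limma, their p-values lay between 0.194 and 0.267.

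By type, the 4 events past adjustment were all annotated as intron retention, against 16.2% of the other events (Fisher's exact test, two-sided, adjusted p = 0.00763), although 3 of the 4 are from PTP4A2. The 4 events lie in 2 genes, so this test counts linked events as separate. Intron retention made up 18.9% of the 689 events without adjustment and 15.7% of the other events, which did not pass (Fisher's exact test, adjusted p = 0.121). Among the 689 events without adjustment, alternative 5' and 3' splice sites were less frequent than among the other events (4.50% against 8.67%, adjusted p = 0.00134, and 7.69% against 11.4%, adjusted p = 0.0227). Genes with a splicing event and genes that changed in expression overlapped no more than chance gives at this size: of 1888 genes tested in both, 141 had an unadjusted p under 0.05 in both, against 129.8 from independent lists (odds ratio 1.17, 95% interval 0.922 to 1.49; Fisher's exact test, two-sided, p = 0.186). After adjustment, 1 gene, MAFK, was in both (Fisher's exact test, p = 0.368).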

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

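Cyclic loess normalization, the crossed pairing, list tests under other scalings, the alternatives at an unadjusted p and the counts by kind of junction were chosen after the data were seen. RBM10 was lower and past limma's test under every alternative run for it, and of 2271 called genes 1 turned direction, under quantile normalization. The count of lower genes was 322 without a filter on low values, where more genes were tested, and 413 to 657 with a library left out; the higher count was 796 with the filter at 5 RPKM, where fewer were. At least 2-fold changes numbered 243 higher and 30 lower, or 544 and 58 with a pseudocount of 0.1. Gene lists past camera numbered 6 under quantile normalization, 6 under cyclic loess normalization and 0 with an estimated correlation; the ribosomal protein list turned direction under cyclic loess normalization (adjusted p = 0.925). The median log2 change of that list was -0.104 as deposited and 0.0261 under cyclic loess normalization. Its deposited value is close to the median log2 ratio of -0.105 over all 680 genes at the highest level. The call of the list as lower is thus not set apart from the shift with expression level. A cause was not tested.

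With the replicate number as a block, 438 lower genes were called, 35 splicing events were higher and 27 lower, and 13 cassette exons were more and 2 less included after adjustment. Replicates of the same number deviated in opposite directions over genes (correlation across genes -0.444; over events -0.0396), so the numbers are not taken to pair the libraries. Under the crossed pairing as a block, 2466 genes were higher and 1730 lower, 4 splicing events were higher and 2 lower, and 1 cassette exon was more included.

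Lower splicing events numbered 0 on the logit scale and 0 with 1 event per gene, and both directions were at 0 to 0 with any library left out, where little power is left and a lone library is assumed to vary like the other group. Without adjustment, 347 events were higher and 342 lower, 163 cassette exons were more and 92 less included, and 2 event types passed in place of 1. These events numbered 455 with 1 per gene and 310 to 374 with a library left out, and the share of more included exons stayed between 60.3% and 72.4% under other settings at an unadjusted p, and was 60.5% from inclusion junctions only and 79.3% from skipping junctions only. Among values that did not pass limma's test, RBM6 expression ranged from -0.237 to 0.0216 with a library left out, an event of NUMB from -0.179 to 0.0581 and an RBM6 event from -0.133 to 0.0312, so their directions are open. Of 1413 comparisons of named, called genes with an alternative, 1279 kept direction and call, 134 lost the call and 0 turned. Depth limits the genes at low levels, and the unknown number of reads per junction limits single PSI values.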

Other observations

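The tests of a single scaling factor, of depth and of fibroblast RNA, and those on the 3' UTR word, were chosen after the result was seen, as were the counts from inclusion junctions alone, while the other tests on cassette exons were written before their results.

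Gene lists not described so far did not pass camera (adjusted p between 0.172 and 0.966), though the cholesterol, ATF4 and MAPK lists passed fry (adjusted p = 0.0208, 0.0234 and 0.0234). They held genes that passed limma's test. Among interferon-stimulated genes, ISG15 rose from 0.879 ± 0.177 to 3.11 ± 1.19 RPKM and OAS1 fell from 4.74 ± 0.0815 to 3.06 ± 0.386 RPKM (SD, n = 2 each); 3 of 9 rose and 1 fell. Of 10 gastric and hepatic lineage genes, which A549 cells express in part, 1 rose and 3 fell: GKN1 rose from 0.360 ± 0.120 to 2.33 ± 0.359 RPKM, and FGA, a fibrinogen chain, fell from 15.5 ± 0.284 to 6.80 ± 0.269 RPKM. Of 6 alveolar lineage genes, ABCA3, of surfactant secretion, rose from 1.49 ± 0.0342 to 3.16 ± 0.0465 RPKM and FOXA2 fell from 2.64 ± 0.111 to 1.33 ± 0.279 RPKM. ISG15, OAS1 and FOXA2 did not pass without a filter on low values. Among MAPK-responsive genes, DUSP5 rose from 12.6 ± 0.934 to 24.7 ± 0.923 RPKM, cyclin D1 (CCND1) fell from 21.1 ± 0.947 to 15.2 ± 1.03 RPKM, and the ligand AREG fell (log2 change -0.80, SE 0.10); 2 of 10 rose and 3 fell, and the list's median (0.01) and mean (-0.07) differ in sign. Among immediate early genes, 5 of 13 rose, DUSP1 from 74.3 ± 1.49 to 133 ± 12.6 RPKM, and 1, FOSL1, fell.

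Of 11 BCL2-family genes, 2 rose and 1, BCL2A1, fell (log2 change -0.93, SE 0.13). YAP and TEAD targets rose in 4 and fell in 3 of 15 cases, cholesterol synthesis genes in 3 and 1 of 19, ATF4 and unfolded protein response genes in 4 and 0 of 20, and nuclear OXPHOS genes in 0 and 3 of 30. These counts depend on scaling: under quantile normalization 2 and 3 YAP and TEAD targets, 1 and 0 ATF4 genes and 2 and 3 OXPHOS genes rose and fell, and 3 immediate early genes rose. Of 8 neighbours of RBM10 on the X chromosome, 3 rose and 0 fell. Markers of cell types other than A549 were mostly below the filter: 4 of 4 tested fibroblast genes rose (COL3A1, COL1A1, MMP2 and THY1), CD68 rose from 1.64 ± 0.117 to 3.53 ± 0.0571 RPKM, NEFL rose from 0.463 ± 0.0172 to 1.29 ± 0.0976 RPKM, and 0 endothelial genes could be tested.

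A PSI of 0 for reads into introns was more frequent in wild type (70 and 76 events in replicates 1 and 2) than in knockdown (56 and 31). Most of this difference came from knockdown replicate 2. Among 300 retention events, 34 had a PSI of 0 in both wild-type libraries and above 0 in both knockdown libraries, 4 the reverse, and 5 to 21 the same for other pairs of libraries. The 34 events lie in 27 genes, of which 16 were higher and 0 lower in limma's test, with a median log2 change of 0.41.

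Genes at low levels had higher values in the knockdown libraries. The median log2 ratio of knockdown to wild type fell from 0.53 in the 2218 lowest genes to -0.10 in the 680 highest, a difference of 0.634, while medians between libraries of a group stayed within 0.11, which argues against a single scaling factor. Greater depth is argued against by the knockdown libraries having 90.5% of the mean relative depth of the wild-type libraries. An effect of lower depth was not tested. Fibroblasts are rich in the collagens that rose. Their transcripts COL6A3, LUM, PDGFRA and PDGFRB had knockdown means of at most 0.155 RPKM, 0.902% of COL3A1. This argues against fibroblast RNA as the main source of COL3A1. The same transcripts rose in knockdown, though, LUM from 0.0124 and 0.0376 RPKM to 0.134 and 0.177 RPKM, while FAP showed no clear change. A trace of fibroblast RNA thus stays possible among genes at low levels. Open explanations include loss of RBM10, the transduction and the selection, which are confounded with the groups and were not tested apart. The share of higher calls may thus depend in part on which scaling is right, from 68.5% as deposited to 52.5% under quantile normalization.

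Cassette exons with higher inclusion outnumbered those with lower inclusion. A general rise in PSI of examined junctions is argued against by exons read through their skipping junction, of which 77.1% (54 of 70) were less skipped (95% Clopper-Pearson interval 65.6% to 86.3%), and a general fall by inclusion junctions alone, with 60.5% of exons more included (53.4% to 67.3%). Among exons that differ by 0.1 or more, 57.7% were more included in knockdown (54.4% to 61%), while the other splits of the libraries, which the authors' filter treats alike, gave 49.9% and 46.3%, with intervals that include 50%, and inclusion junctions alone gave 55.8% (52% to 59.5%). Lower depth is argued against by knockdown replicate 1, the shallowest library, with 49% more included than in replicate 2 (45.1% to 52.8%), and each knockdown library against each wild-type library gave 55% to 57.4%. A hypothesis that goes with these values is that RBM10 represses inclusion of many of these exons, as it is known to do at others. Restoring RBM10 in the knockdown cells would test whether the differences depend on RBM10. It would not tell direct action on these exons from indirect action, and neither was tested here. An effect of transduction or selection also stays open and untested.

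Genes with the word TCCACAT in the 3' UTR (1022 of 9410) had lower values in knockdown, by a log2 difference of -0.07 (t = -5.95), the lowest t of 15246 words, where 100 permutations of the genes gave -4.39 at the lowest. The highest, 5.48, was for AATCCGC in 106 genes. The permutations treat genes as independent. With wild-type replicate 2 and knockdown replicate 1 against the others, TTTATAT had a t of -4.59, below that of any permutation. The permutations thus understate the spread of t and do not exclude chance for TCCACAT. The word occurs in the 3' UTR of RBM10 itself, in exon 24 of 24 (chromosome X, 47186620 to 47186626, hg38), in 4 of 4 coding transcripts, followed there by G, so a candidate explanation is a seed match to the guide strand of the shRNA, although 18.6% of all words occur in an RBM10 coding transcript. The mean change was lower by a further -0.0869 (SE 0.029) where the word was followed by A, as microRNA-like sites are known to favour (151 genes with 1 site, against 716 with another base), while 155 genes with 2 or more sites, expected to change more, had a mean of -0.0893 against -0.124 for 1 site followed by A. Base composition beyond GC content, which was a covariate, is argued against by words of the same bases in another order, with a median t of 0.327. A difference between replicates within the groups is argued against by the other splits, with a t of -0.826 at the lowest. Each knockdown library against each wild-type library gave a t of -6.17 to -5.15, but the word was chosen on the mean of these contrasts. A culture or handling difference between the groups, unrelated to RBM10, would give the same values and stays open. A microRNA with this seed or RBM10 binding stays open and was not tested, and the shRNA sequence was not used here. Direct action through this word could account for few of the lower genes. Of the 672 lower genes searched, 13.2% had the word, against 10.7% of others (Fisher's exact test, p = 0.0458). The word was chosen on the same changes, so this p-value is descriptive and no support for the word. Of the 12 genes with the largest decreases only RBM10 had it, CES1P1 not being searched. Changes downstream of a repressed gene and other sites of the shRNA were not counted.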
